A study of Homo sapiens with 26 samples.

How the data were processed

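RNA from human pancreatic ductal adenocarcinoma and from adjacent normal pancreas was measured on 26 Affymetrix exon arrays. Per the labels' protocols, total RNA of frozen surgical specimens was converted to sense cDNA and labelled with biotin. The groups were taken from the labels: 6 tumours resected after neoadjuvant chemoradiation, 10 tumours resected without prior treatment (called surgery-only tumours), and 10 specimens of adjacent normal pancreas. The labels placed the 26 specimens in 24 patients, 2 of whom gave both a surgery-only tumour and an adjacent normal specimen. The main model and the permutations of list scores did not include the patient. The drugs, radiation dose and interval before surgery were not given in the sources used here.

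The authors deposited a table of log2 expression values, with 22011 probe sets in rows and the 26 arrays in columns. The submitters' processing notes name Partek and RMA (robust multi-array average, which corrects background, normalizes arrays to each other and summarises the probes of a probe set on the log2 scale). The versions and settings of these tools, and the level at which probes were summarised, were not given in the sources used here. The deposited values ran from 2.18 to 14.16, and no pair of arrays held identical values. Array medians lay between 4.87 and 5.34. Scan dates, array batches and the RNA integrity of each array were not given in the sources used here, so none was modelled.

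Probe sets were named from the platform annotation. Of the 22011 probe sets, 14432 carried 1 gene symbol, 2408 carried several and 5171 carried none. Of those with 1 symbol, 14404 matched the reference gene table by gene identifier and 0 symbols needed an update. No gene was named from a probe set with several symbols or none. Where a gene had more than 1 probe set, the probe set with the highest mean over all arrays stood for it, which left 14215 genes. Called probe sets of 1 gene pointed in opposite directions for 0 genes in the comparison of the tumour groups, 0 in surgery-only tumours against normal, and 1 in neoadjuvant tumours against normal. A set of 43 probe sets of sex-linked genes was left out, and 21968 were tested.

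The main test was a linear model of the 3 groups over all 26 arrays with moderated variances (limma 3.58.1 in R 4.3.3, lmFit and eBayes), with a contrast for each pair of groups. P-values were two-sided, were adjusted by the Benjamini-Hochberg method over the 21968 probe sets of a contrast, and were called at 0.05. No pseudocount was added and no filter on dim probe sets was applied. Fold changes are differences of log2 means, and errors are limma's standard errors (SE) unless marked as standard deviations (SD). On simulated data made from these arrays, with 200 of 21968 probe sets shifted, the test recovered 53.5% of shifts of 1 on the log2 scale in neoadjuvant against surgery-only tumours and 94.5% of shifts of 2. For surgery-only tumours against normal it recovered 58% and 94.5%, and for neoadjuvant tumours against normal 48.5% and 90%. The simulated noise was independent between probe sets and equally wide on every array, so these shares may not hold for the real arrays. The number of arrays limits the precision: the median SE of a log2 fold change was 0.25 for both contrasts with the 6 neoadjuvant tumours and 0.21 for the other.

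Gene lists covered 20 cell types or tumour subtypes and 15 processes. The score of a list on an array was the mean log2 value over its measured genes. Differences of scores were tested with a two-sided permutation test, exact over all 8008 splits where a group had 6 arrays and with 100000 resamples for 10 against 10, with Benjamini-Hochberg adjustment over the 35 lists of a contrast. On 200 simulated lists for neoadjuvant against surgery-only tumours, the test called 93.5% of lists shifted by 1 and 4.5% of unshifted lists at an unadjusted p under 0.05. Scores of several real lists varied more between arrays than the simulated ones, with an SD of 1.22 and 0.79 for islet genes in these groups. Real lists were also called after adjustment, so for such lists 93.5% overstates what the test could detect. Members were counted as risen or fallen from limma's p-values, adjusted over all probe sets and, separately, adjusted over the list alone. The competitive test camera was run with a preset correlation of 0.01 between genes and with an estimated correlation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the list tests.

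The groups, the tests, the gene lists, the rule for named genes and the other settings tried were fixed before the data were examined. The rule named, per contrast, up to 12 genes with the largest rise and 12 with the largest fall among those called (the 10 with the smallest p, as values, where none was called). It also took up to 4 called members of each list with the largest absolute change, or, where none was called, the 2 members with the largest absolute change as values, and a fixed set of 12 genes. ACTA2 and INS belonged to that fixed set, had no probe set with 1 symbol, and are not analysed here. Alternatives changed the arrays in the fit, the variance prior, array weights, filters, the normalization, the scaling, the test, a block for sample number or patient, and the probe set of a gene, and left out each array in turn. Further settings left out the 2 arrays of narrowest spread, left out adjacent normal arrays 1 and 4, because several of their list scores stood apart from the other 8, left out surgery-only arrays 3 and 7, because their acinar scores lay in the range of normal, left out the normal arrays of the 2 patients with both specimens, used the spread of each array as a covariate, or averaged the simulated covariances over 100 splits. These were chosen after seeing the data.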

Results

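Expression was profiled in 6 pancreatic ductal adenocarcinomas resected after neoadjuvant chemoradiation, 10 surgery-only tumours resected without prior treatment, and 10 specimens of adjacent normal pancreas. The specimens were bulk tissue, so each array measured a mixture of tumour, stromal, immune and remaining pancreatic cells. Values are log2 expression as deposited. The first principal component held 31.9% of the variance and the second 21.3%. Acinar markers, genes of the enzyme-secreting cells of the pancreas, had a mean score of 10.95 ± 2.25 (SD, n = 10) in adjacent normal, 6.91 ± 2.90 (SD, n = 10) in surgery-only tumours and 4.97 ± 1.12 (SD, n = 6) in neoadjuvant tumours. A few arrays lay apart from their group. The acinar score was 8.33 on adjacent normal array 1 and 5.43 on adjacent normal array 4, against 11.72 to 12.14 on the other 8 normal arrays. It was 11.89 and 11.82 on surgery-only arrays 3 and 7. The log2 values of neoadjuvant array 1 had an SD of 1.62 and those of surgery-only array 6 an SD of 1.70, against 1.85 to 2.18 on the other 24 arrays. Their limma array weights were 0.13 and 0.17, against 0.41 or more on the others, and both arrays stayed in the main comparisons.

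**Figure D1:**
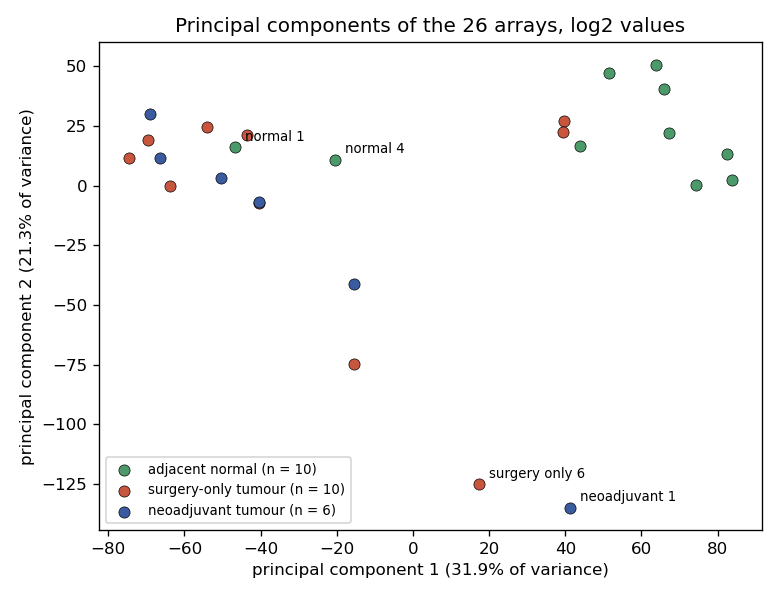
Principal components of the 26 arrays, with each point an array coloured by group and the axes giving the first component (31.9% of variance) and the second (21.3%). Adjacent normal arrays 1 and 4 lie among tumours, and surgery-only arrays 3 and 7 lie on the side of the normals on the first component. Neoadjuvant array 1 and surgery-only array 6 lie lowest on the second component (-135 and -125), with surgery-only array 9 next (-74.9).

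The first comparison asked how tumours resected after chemoradiation (n = 6) differed from surgery-only tumours (n = 10). Islet endocrine genes, which mark the hormone-secreting cells of the pancreas, showed the largest gap of any list in which neoadjuvant tumours were higher. Their score was 7.12 ± 1.22 (SD, n = 6) in neoadjuvant and 5.19 ± 0.79 (SD, n = 10) in surgery-only tumours, a difference of 1.92 on the log2 scale, and 4 of the 6 neoadjuvant arrays lay above all 10 surgery-only arrays. All 17 measured members had a higher mean in neoadjuvant tumours. Of these, 0 passed over all probe sets and 14 rose adjusted over the list alone. TTR, the thyroid hormone carrier transthyretin, differed by 3.40 ± 1.01 (SE) and SLC30A8, the zinc transporter of insulin granules, by 2.95 ± 0.71 (SE). The exact permutation p of the list was 0.0015 and 0.0524 after Benjamini-Hochberg adjustment over 35 lists, just above the threshold. Camera with an estimated correlation gave an adjusted p of 0.00743 for this list. Leaving out neoadjuvant array 2 or 6 or surgery-only array 1, 3 or 7 brought the exact permutation adjusted p to 0.0466, 0.035, 0.0489, 0.0489 and 0.0489. Over all 16 omissions it ran from 0.035 to 0.175, the highest value without neoadjuvant array 3 or 5, where the difference was 1.645 and 1.615. It was 0.0612 with quantile normalization and 0.105 with median centring, and 0.0219 with standardized members and 0.0393 with medians over members. Without surgery-only arrays 3 and 7, a setting added after seeing the data, the difference was 2.16 with an exact permutation adjusted p of 0.0466. With the exact permutation test 0 of 35 lists passed, 3 others beside the islet list having an unadjusted p under 0.05, while camera called 15 with a preset correlation and 2 with an estimated one, and fry called 1.

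At the level of single genes, SCGB2A1, a member of the secretoglobin family of secreted proteins, was the sole probe set called among 21968. It rose by 1.16 ± 0.19 (SE), which is 2.23-fold, with an adjusted p of 0.0327 by limma and Benjamini-Hochberg. No call remained without dim probe sets, probably because SCGB2A1 was itself one of them. At an unadjusted p under 0.05 there were 1093 probe sets, 528 of them higher, where 1098 would be expected by chance. That count was 2084 with array weights, 2024 with array spread as a covariate (a setting added after seeing the data) and 1625 without surgery-only array 6. The exact rank-sum test called 0 and had 862 at an unadjusted p under 0.05. The SCGB2A1 call was lost when neoadjuvant array 1, 3, 4 or 5 or surgery-only array 2, 3, 4, 5, 9 or 10 was left out, with adjusted p up to 0.244. Without neoadjuvant array 6, 28 probe sets were called, without surgery-only array 6, 4, and without neoadjuvant array 2 or surgery-only array 8, 2, while array weights gave 120, 110 of them higher.

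Targets of the tumour suppressor p53 had a slightly higher score in neoadjuvant tumours, by 0.23 on the log2 scale, with an exact permutation p of 0.0288 and 0.336 after adjustment over the lists. Over all probe sets 0 of 24 members passed, and 4 rose adjusted over the list alone. SPATA18 differed by 1.04 ± 0.21 (SE) and ZMAT3 by 0.81 ± 0.21 (SE), with limma adjusted p of 0.112 and 0.312. CDKN1A, which encodes the cell cycle inhibitor p21, differed by 0.53 ± 0.30 (SE), and MDM2, the ubiquitin ligase of p53, by 0.34 ± 0.39 (SE). Camera with an estimated correlation gave this list an adjusted p of 0.0405, and without neoadjuvant array 2 its exact permutation adjusted p was 0.0466. The list passed in no other single omission, and its difference ran from 0.16 without neoadjuvant array 5 to 0.31 without neoadjuvant array 2. In relations chosen after seeing the data, the p53 and islet scores of the 6 neoadjuvant arrays had a Pearson r of 0.796 (exact permutation p 0.0736, adjusted p 0.294 over 4 relations) and a Spearman rho of 0.771 (exact permutation p 0.103). Pearson's r was 0.627 without the 2 arrays farthest from the median islet score. With adenocarcinoma epithelium Pearson's r was -0.671 (exact permutation p 0.15, adjusted p 0.3) and Spearman's rho -0.714 (exact permutation p 0.136), and r was 0.269 without the 2 farthest arrays. Within the 10 surgery-only arrays r was -0.0694 with islet and -0.0565 with epithelial scores (permutation p 0.846 and 0.874, adjusted p 0.874 for both), rho was -0.0667 and -0.0424 (permutation p 0.866 and 0.919), and r was 0.206 and 0.223 without the 2 farthest arrays. Schwann cell and nerve genes differed by 0.53, exact permutation p 0.0203 and 0.336 adjusted, and 0.035 adjusted without neoadjuvant array 6. The difference was 0.32 without neoadjuvant array 3, and the list passed in no other single omission. Of 9 members, 0 passed over all probe sets and 5 rose adjusted over the list alone. The sodium channel SCN7A differed by 1.40 ± 0.59 (SE) and the glial ligand receptor GFRA3 by 1.09 ± 0.38 (SE).

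Acinar genes differed by -1.94 on the log2 scale in neoadjuvant against surgery-only tumours, with an exact permutation p of 0.146 and 0.538 after adjustment. All 20 members had a lower mean in neoadjuvant tumours, and 0 passed over all probe sets or adjusted over the list alone. The digestive proteases CPA1 and CPB1 differed by -3.39 ± 1.60 (SE) and -3.32 ± 1.53 (SE). Genes of normal duct cells differed by -0.74, with the chloride channel CFTR at -1.77 ± 0.77 (SE) and SPP1, which encodes osteopontin, at -1.61 ± 0.64 (SE). Neither list passed. Surgery-only arrays 3 and 7, whose acinar scores lay in the range of the 8 normal arrays, carried much of both differences, which were -0.70 and -0.34 without them.

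The lists of tumour epithelium, stroma and cell division did not pass either. The differences were 0.28 for adenocarcinoma epithelium, 0.49 for the classical subtype, -0.29 for the basal-like subtype, -0.17 for activated fibroblasts and 0.74 for inflammatory or quiescent fibroblasts. They were -0.10 for TGF-beta targets, -0.09 for epithelial-mesenchymal transition, -0.26 for proliferation, -0.16 for DNA repair and -0.16 for nucleoside and fluoropyrimidine handling. KRT7, a keratin of ductal epithelium, differed by -1.28 ± 0.54 (SE), and CDA, which inactivates gemcitabine, by -1.54 ± 0.54 (SE). The proliferation marker MKI67 differed by -0.38 ± 0.51 (SE), TYMS, the target of fluorouracil, by 0.05 ± 0.34 (SE), or -0.02 with quantile normalization, KRT19 by -0.18 ± 0.60 (SE) and COL1A1 by 0.23 ± 0.66 (SE).

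No immune list passed between the tumour groups. The differences were 0.10 for T cells, 0.09 for cytotoxic lymphocytes and NK cells, 0.01 for B cells (-0.03 with quantile normalization), 0.22 for plasma cells, 0.12 for macrophages and monocytes, -0.34 for neutrophils and -0.15 for mast cells. Interferon response genes differed by 0.20, MHC class I by -0.01 (0.05 with quantile normalization), MHC class II by 0.49, checkpoints by -0.08, complement by 0.33 and inflammatory secretion by -0.31. The T cell genes CD3E and CD8A differed by 0.23 ± 0.64 (SE) and 0.03 ± 0.29 (SE), and the macrophage gene CD68 by -0.02 ± 0.58 (SE), or 0.11 with quantile normalization. The remaining lists differed by 0.01 for endothelial cells, -0.39 for smooth muscle and pericytes, 0.19 for adipocytes, 0.48 for red blood cells, -0.41 for hypoxia and glycolysis, -0.33 for endoplasmic reticulum stress and 0.40 for immediate early genes. Single arrays moved many of these values. Plasma cells were 0.09 without neoadjuvant array 1, checkpoints -0.002 without neoadjuvant array 2 and immediate early genes 0.23 without neoadjuvant array 6. Endoplasmic reticulum stress was -0.20 without surgery-only array 3, adipocytes 0.11 without surgery-only array 4 and nucleoside handling -0.10 without surgery-only array 5. Without surgery-only array 5 the differences were -0.01 for inflammatory secretion, -0.01 for neutrophils and -0.21 for hypoxia, without neoadjuvant array 2 0.43 for macrophages, and without neoadjuvant array 1 -0.13 for B cells. The classical subtype was 0.20 without neoadjuvant array 6, and the basal-like subtype -0.10 and interferon response 0.02 without neoadjuvant array 5. Activated fibroblasts were -0.01 without neoadjuvant array 2 and -0.36 without neoadjuvant array 5. Omitting some single array turned the sign for T cells, cytotoxic lymphocytes, B cells, macrophages, mast cells, MHC class I, endothelial cells, adenocarcinoma epithelium, TGF-beta targets and epithelial-mesenchymal transition. Without surgery-only arrays 3 and 7 interferon response was -0.07, activated fibroblasts -0.58, smooth muscle and pericytes -0.63 and proliferation -0.50. In that setting TGF-beta targets were -0.22 and epithelial-mesenchymal transition -0.33, while adenocarcinoma epithelium was 0.07 and the classical subtype 0.28. The islet list alone passed there. A p that misses the threshold does not show that these groups were alike.

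**Figure D2:**
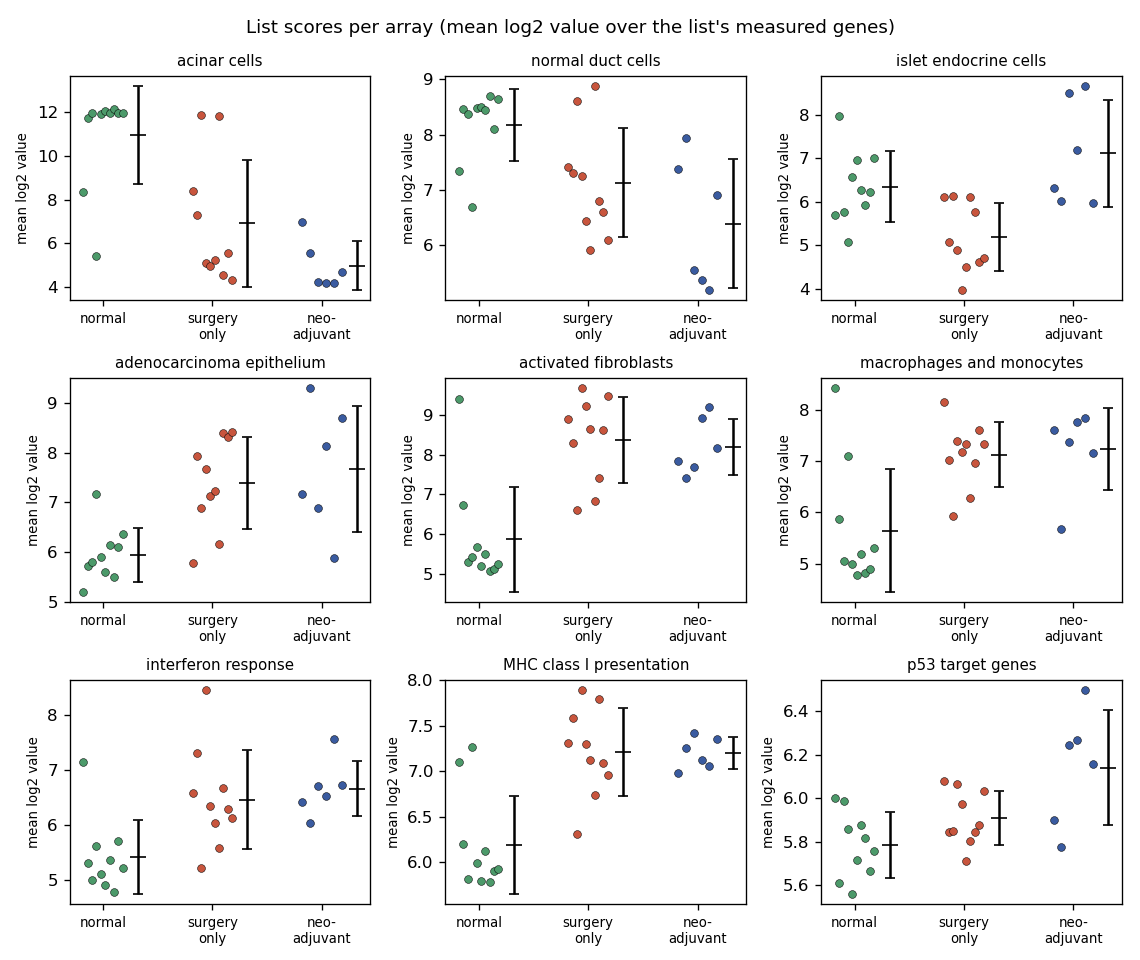
Scores of 9 gene lists on each array (y axis, mean log2 value over the measured genes of the list), with points for the arrays of each group and bars for the mean ± SD. Acinar scores lie highest in adjacent normal, fibroblast and epithelial scores are higher in both tumour groups, and the mean islet score is highest in neoadjuvant tumours. Islet scores of neoadjuvant tumours overlap those of both other groups, and neither comparison passed.

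The second comparison asked how untreated tumours differed from adjacent normal pancreas (n = 10 and 10). Of the activated fibroblast genes 22 of 25 rose, and of the acinar genes 17 of 20 fell, over all probe sets. With an estimated correlation camera gave adjusted p = 0.148 and 0.187 for these lists. POSTN, the matrix protein periostin, rose 18.4-fold (4.21 ± 0.77 SE on the log2 scale), VCAN, the proteoglycan versican, 11.9-fold and COL1A1, the main fibrillar collagen, 10.7-fold. CTRL, GP2 and CTRC, a protease, a zymogen granule protein and a protease of acinar cells, fell by 5.44, 5.36 and 5.17 on the log2 scale. Adjusted over the list alone, 20 acinar genes fell. In all, 2031 probe sets were called by limma and Benjamini-Hochberg, 1096 higher and 935 lower, and 623 and 433 of these changed at least 2-fold. The majority turned under other settings, with 859 higher and 1207 lower after median centring, 1187 and 1330 after quantile normalization, and 3318 and 4965 with array weights.

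Activated fibroblast genes had a score of 8.37 ± 1.07 (SD, n = 10) in surgery-only tumours and 5.87 ± 1.33 (SD, n = 10) in adjacent normal, with an adjusted permutation p of 0.00679. Of 25 members, 22 rose over all probe sets and 23 adjusted over the list alone. FN1, which encodes fibronectin, rose by 3.38 ± 0.58 (SE), SULF1 by 3.36 ± 0.55 (SE) and MMP11, a stromal metalloproteinase, by 3.39 ± 0.67 (SE). The score of TGF-beta targets was higher by 1.07, with 9 of 15 members risen over all probe sets and 10 adjusted over the list alone, among them TGFBI at 2.29 ± 0.49 (SE). Epithelial-mesenchymal transition genes were higher by 1.19, with 7 of 11 members risen over all probe sets and 8 adjusted over the list alone, including the cadherin CDH11 at 2.53 ± 0.55 (SE). The adjusted permutation p of these lists was 0.0056 and 0.00921. With an estimated correlation camera gave adjusted p = 0.148 for activated fibroblasts and for TGF-beta targets and adjusted p = 0.187 for epithelial-mesenchymal transition.

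Genes of adenocarcinoma epithelium were higher by 1.45, with an adjusted permutation p of 0.00679 (adjusted p = 0.187 with an estimated correlation). Of 22 members, 10 rose over all probe sets and 14 adjusted over the list alone. The iron-binding protein LCN2 rose by 3.40 ± 0.80 (SE), KRT7 by 2.87 ± 0.47 (SE) and KRT19 by 2.42 ± 0.52 (SE). SLPI, a secreted protease inhibitor outside the lists, rose 20.4-fold. The basal-like list was higher by 0.97, with 3 of 14 members risen over all probe sets and 4 adjusted over the list alone, adjusted permutation p 0.00731 (adjusted p = 0.262 with an estimated correlation). Hypoxia and glycolysis genes were higher by 0.86, with 7 of 16 members risen over all probe sets, and 10 risen and 2 fallen adjusted over the list alone. Their adjusted permutation p was 0.00731 (adjusted p = 0.187 with an estimated correlation), and the glucose transporter SLC2A1 rose by 2.39 ± 0.46 (SE). Proliferation genes differed by 0.69 with an adjusted permutation p of 0.0526, and 1 of 28 members, TOP2A at 1.47 ± 0.41 (SE), rose over all probe sets and 9 adjusted over the list alone. MKI67 differed by 1.27 ± 0.44 (SE), with a limma adjusted p of 0.069. The proliferation list passed without adjacent normal array 4 (adjusted permutation p 0.00455) or surgery-only array 3 or 7 (0.0287 and 0.0289), and TOP2A missed the threshold without surgery-only array 5 or 10 or adjacent normal array 8 (limma adjusted p up to 0.0515).

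Macrophage and monocyte genes were higher by 1.48, with 9 of 14 members risen over all probe sets and 10 adjusted over the list alone, among them TYROBP at 2.22 ± 0.54 (SE) and CD68 at 2.00 ± 0.50 (SE). Interferon response genes were higher by 1.05, with 12 of 25 risen over all probe sets and 16 adjusted over the list alone, including IFI27 at 2.44 ± 0.43 (SE). MHC class I genes were higher by 1.02, with 8 of 9 risen over all probe sets and 8 adjusted over the list alone, including B2M, the shared light chain, at 1.62 ± 0.25 (SE). Inflammatory and senescence-associated secretion genes were higher by 1.17, with 7 of 20 risen over all probe sets and 10 adjusted over the list alone, among them the urokinase receptor PLAUR at 2.43 ± 0.45 (SE). The adjusted permutation p of these 4 lists was 0.011, 0.0154, 0.00679 and 0.0056. With an estimated correlation camera gave adjusted p = 0.187 for macrophages, interferon response and secretion and adjusted p = 0.148 for MHC class I. Checkpoint genes were higher by 0.39 (3 of 10 risen), complement by 0.50 (7 of 16 risen and 1, C5, fallen) and nucleoside handling by 0.36 (2 of 16 risen). Adjusted over the list alone, 3 rose, 9 rose and 2 fell, and 4 rose in these lists. Their adjusted permutation p was 0.0208, 0.0494 and 0.00824, and adjusted p = 0.231, 0.187 and 0.246 with an estimated correlation. CDA rose by 1.68 ± 0.47 (SE), with an adjusted p of 0.0506 by limma without surgery-only array 5. The complement list missed the threshold when any of 14 arrays was left out (adjusted permutation p up to 0.0896), namely surgery-only 1, 2, 4, 7, 8 or 10 or adjacent normal 3, 4, 5, 6, 7, 8, 9 or 10. With medians over members the checkpoint, complement and nucleoside lists, and the basal-like and adipocyte lists, did not pass. Median centring ended the checkpoint and complement calls, and quantile normalization the complement call. CD3E differed by 0.77 ± 0.55 (SE) and CD8A by -0.13 ± 0.25 (SE), and the T cell list, at 0.27, did not pass. MHC class II genes differed by 1.01 with an adjusted permutation p of 0.062, and passed without adjacent normal array 1 or 4 or surgery-only array 5 (0.00712 at the lowest). Targets of p53 differed by 0.12 with an adjusted permutation p of 0.0964, with 3 of 24 risen and 1 fallen over all probe sets, and 5 risen and 2 fallen adjusted over the list alone. That list passed without adjacent normal array 1 (0.0443).

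The acinar score was lower by 4.04 in surgery-only tumours, with an adjusted permutation p of 0.00998 (adjusted p = 0.187 with an estimated correlation). CPA1 differed by -4.09 ± 1.38 (SE) with a limma adjusted p of 0.06. Without surgery-only arrays 3 and 7 CPA1 fell by 5.36 and passed in limma. Endoplasmic reticulum stress genes were lower by 0.93, with 7 of 15 members fallen over all probe sets, and 11 fallen and 1 risen adjusted over the list alone, including SEL1L, a component of protein quality control, at -2.47 ± 0.54 (SE). Islet genes were lower by 1.16, with 4 of 17 members fallen over all probe sets and 4 adjusted over the list alone, among them the hormone genes IAPP at -3.48 ± 0.93 (SE) and SST at -2.15 ± 0.56 (SE). Normal duct genes were lower by 1.04, with 2 of 10 fallen over all probe sets, and 6 fallen and 1 risen adjusted over the list alone, including the bicarbonate transporter SLC4A4 at -2.81 ± 0.73 (SE). Adipocyte genes were lower by 0.83, with 2 of 10 fallen over all probe sets and 2 adjusted over the list alone. The adjusted permutation p of these 4 lists was 0.00935, 0.0118, 0.0286 and 0.00731, and adjusted p = 0.187, 0.262, 0.323 and 0.194 with an estimated correlation. The duct list missed the threshold without surgery-only array 6 or 10 or adjacent normal array 8 (adjusted permutation p up to 0.0549), and also under fry and without the 2 arrays of narrowest spread.

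With patient as a random block, since 2 patients gave both specimens, 2390 probe sets were called in surgery-only tumours against normal. Without the normal arrays of these patients, a setting added after seeing the data, 2644 were called and 20 lists passed. The count of probe sets called in surgery-only tumours against normal was 4157 without adjacent normal arrays 1 and 4, which were left out after their list scores were seen to stand apart. It was 3553 without surgery-only arrays 3 and 7, also chosen after seeing the data, 3284 without normal array 1 alone, 1341 without normal array 6, 8283 with array weights and 1332 with the rank-sum permutation test.

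The third comparison asked how tumours resected after chemoradiation differed from adjacent normal pancreas (n = 6 and 10). All 20 acinar genes fell over all probe sets and adjusted over the list alone, 20 of 25 activated fibroblast genes rose over all probe sets, and 10 of 22 genes of tumour epithelium rose and 1 fell. With an estimated correlation camera gave adjusted p = 0.144, 0.144 and 0.192 for these lists. CTRL fell by 7.60 ± 1.41 (SE) on the log2 scale and CPA1 by 7.48 ± 1.60 (SE). CEACAM5 rose 27.1-fold (4.76 ± 1.03 SE), the mucin-like gene MUCL3 19.1-fold and LCN2 14.8-fold. By limma and Benjamini-Hochberg 2204 probe sets were called, 929 higher and 1275 lower, of which 585 and 689 changed at least 2-fold.

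The acinar score was lower by 5.98 in neoadjuvant tumours, with an exact permutation adjusted p of 0.0109 (adjusted p = 0.144 with an estimated correlation). Normal duct genes were lower by 1.79, with 6 of 10 members fallen over all probe sets and 6 adjusted over the list alone, among them SLC4A4 at -3.71 ± 0.85 (SE) and CFTR at -3.63 ± 0.77 (SE). Endoplasmic reticulum stress genes were lower by 1.27, with 10 of 15 fallen over all probe sets and 11 adjusted over the list alone, among them SEL1L at -3.07 ± 0.63 (SE) and XBP1, a transcription factor of secretory cells, at -2.49 ± 0.43 (SE). The exact permutation adjusted p was 0.0119 and 0.0117, and adjusted p = 0.192 and 0.144 with an estimated correlation. Islet genes differed by 0.76, exact permutation adjusted p 0.228, and 1 of 17 members, ISL1 at 0.95 ± 0.22 (SE), rose over all probe sets and adjusted over the list alone. The islet difference was 0.46 without neoadjuvant array 5 and 0.99 without neoadjuvant array 6.

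Activated fibroblast genes were higher by 2.33, with 20 of 25 members risen over all probe sets and 22 adjusted over the list alone, including COL1A1 at 3.65 ± 0.66 (SE) and VCAN at 3.63 ± 0.69 (SE). Adenocarcinoma epithelium was higher by 1.73, with 10 of 22 risen and 1 fallen over all probe sets, and 15 risen and 2 fallen adjusted over the list alone, among them GPX2, a glutathione peroxidase, at 3.55 ± 0.64 (SE). Interferon response genes were higher by 1.25, with 12 of 25 risen over all probe sets and 16 adjusted over the list alone, including MX2 at 2.33 ± 0.51 (SE). These 3 lists had an exact permutation adjusted p of 0.0119, and adjusted p = 0.144, 0.192 and 0.192 with an estimated correlation. MHC class I was higher by 1.01 (5 of 9 risen, 7 adjusted over the list alone), with B2M at 1.91 ± 0.29 (SE). Complement was higher by 0.83 (6 of 16 risen and 1 fallen, 10 and 2 adjusted over the list alone), and TGF-beta targets by 0.97 (6 of 15 risen, 6 adjusted over the list alone). These had an exact permutation adjusted p of 0.0135 and adjusted p = 0.144 with an estimated correlation.

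The p53 target list was higher by 0.36 in neoadjuvant tumours than in normal, with an exact permutation adjusted p of 0.0135 (adjusted p = 0.144 with an estimated correlation). Of 24 members, 8 rose and 2 fell over all probe sets, and 12 rose and 3 fell adjusted over the list alone. The death receptor genes TNFRSF10B and FAS rose by 1.59 ± 0.31 (SE) and 1.35 ± 0.32 (SE), while TP53INP1 fell by 1.30 ± 0.42 (SE). The TP53INP1 call was lost when any of 13 arrays was left out, all but adjacent normal 1, 4 and 5 (limma adjusted p up to 0.107). CDKN1A differed by 0.69 ± 0.30 (SE) and MDM2 by 0.44 ± 0.39 (SE), and neither passed. Schwann cell and nerve genes were higher by 0.48, with 2 of 9 risen over all probe sets, S100B at 1.26 ± 0.34 (SE) and GAP43 at 0.74 ± 0.22 (SE), and 3 adjusted over the list alone. That list had an exact permutation adjusted p of 0.0222 (adjusted p = 0.248 with an estimated correlation). The Schwann list missed the threshold without neoadjuvant array 3 or 4 (exact permutation adjusted p 0.0692 and 0.0544), S100B without neoadjuvant array 3 (limma adjusted p 0.0738) and GAP43 without neoadjuvant array 2 or 3 or adjacent normal array 8 (up to 0.0966). With median centring of the arrays 11 lists passed, against 17, the 6 lost being p53 targets, Schwann cells, macrophages, MHC class II, epithelial-mesenchymal transition and hypoxia. Quantile normalization also ended the Schwann call.

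Further lists that passed in neoadjuvant tumours against normal were macrophages and monocytes at 1.60, MHC class II (9.15 ± 0.44 against 7.65 ± 1.23, SD, n = 6 and 10), epithelial-mesenchymal transition at 1.10, inflammatory secretion at 0.86, basal-like genes at 0.68 and hypoxia at 0.44. Over all probe sets the members risen were 8 of 14, 2 of 7, 3 of 11, 4 of 20, 1 of 14 and 3 of 16, with 1 hypoxia gene, BNIP3, fallen. Adjusted over the list alone 13, 6, 5, 4, 3 and 5 rose, and 2 hypoxia genes fell. The exact permutation adjusted p was 0.0365, 0.0365, 0.0296, 0.0109, 0.0328 and 0.0365. With an estimated correlation they had adjusted p = 0.192, 0.192, 0.211, 0.355, 0.544 and 0.555. HLA-DRA, an MHC class II chain, rose by 1.78 ± 0.42 (SE), and the complement protease C1S by 2.18 ± 0.51 (SE). Single omissions ended the calls of 5 of these lists, with exact permutation adjusted p up to 0.083, 0.0674, 0.0616, 0.09 and 0.101 in the order macrophages, MHC class II, epithelial-mesenchymal transition, basal-like and hypoxia. The macrophage and MHC class II calls were lost without neoadjuvant array 1, 3, 4, 5 or 6 or adjacent normal array 3, 5, 6, 7, 8, 9 or 10, and the transition call without neoadjuvant array 3, 4 or 5 or adjacent normal array 8. The basal-like call was lost without neoadjuvant array 1, 2, 4 or 6 or adjacent normal array 6, 8 or 10, and the hypoxia call without neoadjuvant array 2, 3, 4, 5 or 6 or adjacent normal array 2, 3, 5, 6, 8, 9 or 10. Without neoadjuvant array 4, 11 lists passed in all. Fry did not call the secretion, basal-like and hypoxia lists. The basal-like and hypoxia calls were lost with standardized members, and the basal-like and macrophage calls with medians over members. The macrophage, MHC class II and basal-like calls were also lost without the 2 arrays of narrowest spread. The classical subtype list differed by 1.08, more than the basal-like list, with an exact permutation adjusted p of 0.153, and passed without adjacent normal array 4 (0.0147). Without adjacent normal arrays 1 and 4 the classical list passed and the basal-like list did not. Proliferation differed by 0.43 and the T cell list by 0.37, and neither passed, though proliferation passed without adjacent normal array 4 (exact permutation adjusted p 0.00799). Without adjacent normal arrays 1 and 4 the count of called probe sets was 4044, without array 1 alone 3381, with array weights 9347 and with the exact rank-sum test 856.

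**Figure D3:**
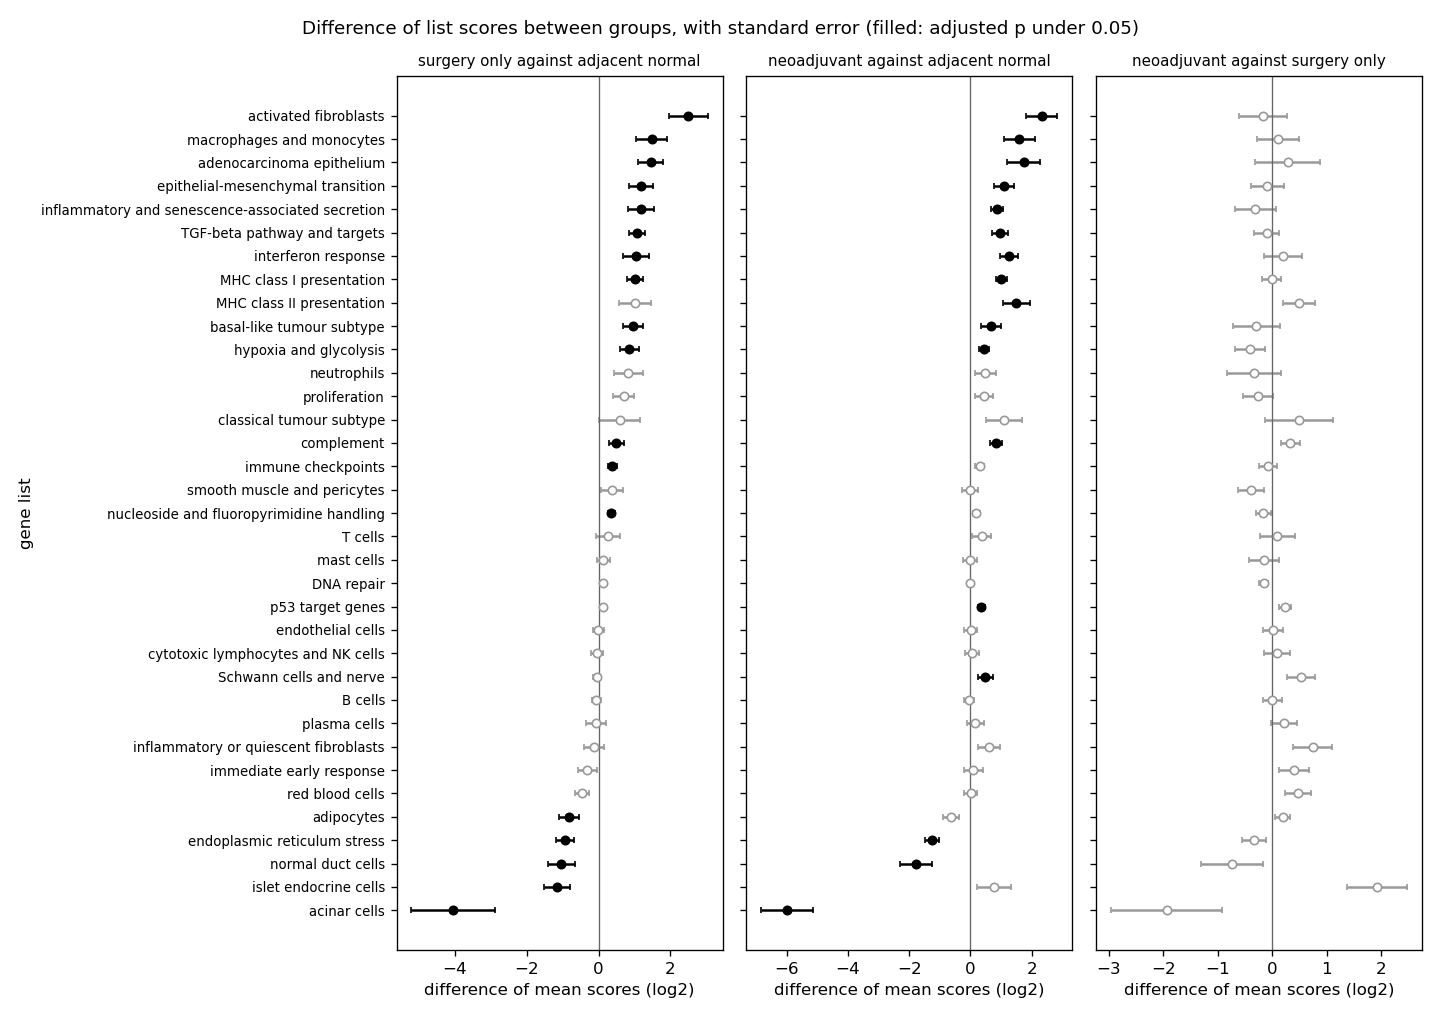
Differences of mean list scores (x axis, log2 scale) for 35 gene lists (y axis) in the 3 comparisons, with bars for the standard error of the difference and filled points for lists with an adjusted p under 0.05. Filled points number 18 for surgery-only tumours against normal, 17 for neoadjuvant tumours against normal and 0 between the tumour groups.

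A last comparison asked whether probe sets that differed between surgery-only tumours and normal pancreas moved further in the same direction, or back, in neoadjuvant tumours. With the surgery-only arrays split 5 and 5 so that no array entered both differences, the mean covariance over 100 splits was 0.0372, and 74 splits were positive. The value lay inside the 95% interval of unchanged groups simulated from the same arrays, which was -0.0756 to 0.0547 for single splits and, in a setting added after seeing the data, -0.0726 to 0.0383 for means over 100 splits. With all surgery-only arrays in both differences the covariance was 0.0057, above the simulated 95% interval of -0.116 to -0.0038 around -0.0384. That value also lay above its interval without dim probe sets (0.0398), with quantile normalization (0.0122) and without acinar and islet genes (0.0005). The means over splits lay above their matched interval without dim probe sets (0.074) and with quantile normalization (0.0402), and inside it without acinar and islet genes (0.0321). The simulated groups also lacked the difference between tumours and normal that the real arrays held. Their intervals may therefore be too narrow for this question, and a value above them does not settle it. These comparisons gave different answers, and genes are not independent replicates, so whether the differences were related was left undecided.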

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

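Tests of the islet list, of the splits with unweighted arrays and of a wrong label for adjacent normal array 4 were chosen only after the result was seen. The array-weight splits and the marker lists of gut tissue were set out before their own results were seen. Of 117 group tests for an array far from the rest of its group, 20 found such an array, where chance gives about 1 in 20, or 5.8. Most fell on 2 adjacent normal arrays. All were list scores, and no array was flagged for its median, its spread or its first or second principal component.

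Adjacent normal array 4 stood above the other normals in the classical tumour subtype list (score 8.30, next 5.80), proliferation (6.21), plasma cells (6.20), nucleoside handling (6.44) and DNA repair (5.43).

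Intestinal mucosa in the specimen is a candidate source for adjacent normal array 4. A list of 20 intestinal genes, 17 measured, averaged 10.26 on this array and at most 4.96 on the other 25, a gap of 5.30, with 16 of the 17 highest on it, all but OLFM4 (12.97 against 13.02), while in surgery-only tumours 1 had a median level and 3 had a mean level above the median of all values, and 0 belonged to another list. The digestive enzyme gene SI reached 12.02 against 4.01 ± 0.56 (SD, n = 9) on the other normals, and the Paneth cell defensins DEFA6 and DEFA5 reached 11.84 and 11.51 against 2.92 ± 0.19 and 2.84 ± 0.21 (SD, n = 9). Gastric mucosa is argued against by a gastric list 1.95 below the highest other array (difference -1.95), and a mislabelled tumour by an activated fibroblast score 1.17 below the lowest surgery-only tumour (difference -1.17). How such tissue may have entered the specimen, and any biological explanation, was not tested.

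Adjacent normal array 1 was highest of its group in activated fibroblasts (9.39), inflammatory or quiescent fibroblasts (7.95), adipocytes (7.03), endothelial cells (6.63), neutrophils (5.48), interferon response (7.14), checkpoints (5.19), TGF-beta targets (7.91) and epithelial-mesenchymal transition (8.41). Surgery-only array 5 was highest in neutrophils (8.09), inflammatory secretion (8.94) and hypoxia (10.06). Neoadjuvant array 1 was highest in B cells (4.52), and neoadjuvant array 2 lowest in macrophages (5.68) and MHC class II (8.29).

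Islet genes were higher in neoadjuvant than in surgery-only tumours by 1.92, with an adjusted p of 0.0524 (exact permutation test) just above the threshold. The 2 arrays of narrow spread do not account for the size, which was 2.01 without them, although with fewer arrays the exact permutation adjusted p was 0.192. A lower acinar share would raise other cell types alike. In neoadjuvant against surgery-only tumours the mean of 5 other non-acinar lists differed by -0.07. The mean of all 18 other cell type lists differed by 0.07, so on average the rise was not shared. The islet score exceeded these means by 1.99 and 1.86 more in neoadjuvant tumours (exact permutation p 0.00437 and 0.00474). It exceeded inflammatory or quiescent fibroblasts, the most raised of the 18, by 1.18 more (exact permutation p 0.00337). The islet list was picked for its large difference, and these p-values are not adjusted for that choice. The excesses over the means mostly restate the 1.92, so they are not separate evidence. Intact pancreas in the specimens would bring acinar genes too. Acinar minus islet scores were lower by 6.75 in neoadjuvant tumours than in adjacent normal (difference -6.75, exact permutation p 0.00025). That value combines the differences of -5.98 for acinar and 0.76 for islet genes given above. A low acinar score alone would produce it, so it adds no separate evidence and bears only on pancreas with its acini in place. Pancreas that lost acini and kept islets, or an effect of treatment on the tumour, may remain open and was not tested. Neoadjuvant arrays 5 and 3 had the highest islet scores (8.66 and 8.51) and the lowest adenocarcinoma epithelium scores (5.88 and 6.88). Arrays 2 and 6 had the lowest islet scores (6.03 and 5.98) and the highest epithelium scores (9.305 and 8.70). Arrays 1 and 4 lay between in both lists. This was seen after the fact, and the share of tumour in each specimen was not tested.

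With array weights 120 probe sets separated the tumour groups, and 9 of 100 splits of the same 16 arrays gave as many, the highest other split calling 2239. Without weights 1 probe set was called, 8 of 100 splits gave as many and the highest other called 1174, so chance cannot be excluded for either count. Splits that call several times the real count may reflect a structure of the samples or genes that vary together, and neither was tested. For surgery-only tumours against normal, 2 of 100 splits called as many as the real 2031, with a highest other of 2614, and for neoadjuvant tumours against normal 1 of 100 did, the real split with 2204, with a highest other of 1136. The share of splits was under 0.05 for both counts. With only 100 splits, and 1 other split of surgery-only and normal arrays above the real count, chance was not excluded for that contrast. The splits also took no account of the 2 patients with both specimens.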

How the results depend on the processing

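The settings that left out the 2 arrays of narrowest spread or normal arrays 1 and 4 or surgery-only arrays 3 and 7 or the normals of patients with both specimens, or used array spread as a covariate, or averaged simulated values over splits, were chosen only after the result was seen. For neoadjuvant against surgery-only tumours the 1 called probe set became 120 with array weights, 2 with quantile normalization and 3 with median centring. It became 0 with only these groups in the fit, without dim or less variable probe sets, with the acinar covariate, without the arrays of narrowest spread and with rank sums, and leaving out each array gave 0 to 28. Without dim probe sets 10988 were tested. The limma p of SCGB2A1, 1.49e-06 in the main fit, would pass among these, so that filter probably removed the probe set itself. For surgery-only tumours against normal the 2031 became 8283 with array weights, 1056 at a 2-fold minimum, 1332 with rank sums, 3296 with the spread covariate and 4157 without normal arrays 1 and 4, and leaving out each array gave 1341 to 3284. For neoadjuvant tumours against normal the 2204 became 9347, 1274, 856, 4214 and 4044 in the same settings, and leaving out each array gave 1475 to 3381. Without surgery-only arrays 3 and 7 the 2031 became 3553. Median centring moved the share of higher calls from 54% to 41.6% and from 42.2% to 34.2%. Array weights moved the median fold change to -0.12 and -0.14 in these contrasts. The causes were not tested.

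No list passed between the tumour groups, 1 passed with standardized members, with medians over members, without surgery-only arrays 3 and 7 and with fry, 2 with camera and an estimated correlation and 15 with a preset correlation of 0.01, and leaving out each array gave 0 to 2. The 18 lists of surgery-only tumours against normal and the 17 of neoadjuvant tumours against normal became 0 and 0 with camera and an estimated correlation, and the 17 became 11 with median centring. Leaving out each array gave 16 to 22 and 11 to 20. Smooth muscle and pericyte genes turned from -0.02 to 0.32 in neoadjuvant tumours against normal without normal arrays 1 and 4. The covariance of the last comparison rose from 0.0372 to 0.074 without dim probe sets, above its simulated interval. With simulated values averaged over 100 splits it lay above the interval with quantile normalization too (0.0402). Over the other settings and single lists, 2656 values kept their direction and side of the threshold, 130 fell below it, 114 rose above it and 144 below the threshold changed sign; for named genes these were 8058, 583, 141 and 56.

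Sample numbers were not used as a pairing. Of the 2 patients with both specimens 1 had the same number on both. The correlation of deviations exceeded 0.1 in 6 of 10 same-numbered pairs of surgery-only and normal arrays. It did so in 1 of 6 pairs of neoadjuvant and normal arrays and 2 of 6 of neoadjuvant and surgery-only arrays. Medians in these pairs were 0.16, -0.11 and -0.10, against -0.04, 0.02 and 0.04 over all pairs of arrays from the same groups. The correlations alone do not argue against a pairing of surgery-only and normal arrays, but the patient labels do. By these labels only 1 of the same-numbered pairs of surgery-only and normal arrays came from 1 patient, and the others joined different patients. With patient as a random block (correlation 0.411) the counts were 1, 2390 and 2193. With sample number as a block, 0 probe sets were called between the tumour groups, 1738 in surgery-only tumours against normal and 699 in neoadjuvant tumours against normal. Camera with the block and the preset correlation of 0.01 gave 18, 21 and 21 lists, against 15, 21 and 21 at that correlation without the block. With an estimated correlation and no block camera gave 2, 0 and 0. The number of arrays limits the precision.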
